A study of Mus musculus with 6 samples.

How the data were processed

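RNA was sequenced from mouse spleen, with 3 libraries titled as virtual memory CD8 T cells (TVM) and 3 as central memory CD8 T cells (TCM). The labels' extract protocol describes homogenised tissue and total RNA and does not describe a sort or gate, so the cells are named here by the sample titles. Libraries followed standard Illumina protocols per the labels, and the strand setting is not given in the sources used here. The authors deposited 1 table of read counts per gene. It holds whole numbers per Ensembl gene with no normalisation, made with HISAT2 2.0.5 and featureCounts per the submitters' processing notes. Those notes list the builds hg38 and mm39 without a role; the gene identifiers are mouse identifiers. The annotation release is not given in the sources used here, and no coordinates are printed because the annotation used for names and biotypes belongs to another build than mm39.

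Each column was matched to its sample by name and no column was left unused. The table had 57180 gene rows, of which 51884 were paired with a symbol through the gene name table and 29891 had no counts in any library. Totals per library ran from 26326971 to 41786184 counts, so a count of 0, read as at most 3 counts, allows 0.0718 to 0.114 CPM; such limits cover counting error only. The labels do not say whether replicates came from separate animals, and p-values measure only the spread between these samples, which may be technical. Replicates were compared before averaging. Pearson's r of log CPM across genes, which are not independent replicates, was 0.945 to 0.984 within groups and 0.886 to 0.921 between groups, and no pair agreed within sampling noise (smallest chi-square per degree of freedom 18.6).

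Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM scaling, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05), coded as TVM minus TCM. The filter left 16180 genes, 15669 with a symbol. The common biological coefficient of variation was 0.30. The test was run on 10 sets of counts simulated for TVM against TCM, with 15643 tested genes in the first set. In each, 200 genes and a further list of 40 genes were changed. A mean of 29.6 of 100 genes changed by 2-fold and 69.6 of 100 changed by 4-fold were called, and 7.23% of calls were false. Calls of the 40 list genes counted as true. Far fewer genes were changed than the data call, so these shares may not hold for the data. The median fitted log2 fold change of the 4-fold genes was off by 0.001.

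Before the data were examined, 29 gene lists were fixed for T cell and NK functions, cytokine signalling, memory and effector programmes, migration, metabolism, proliferation, interferon response, steroid and insulin receptors, and markers of other cell types or of RNA quality. Each list was tested with camera (limma 3.58.1) on the edgeR fit with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Of the 18 lists past the threshold, 0 held with an estimated correlation, which with 6 libraries is poorly determined. Named genes followed a rule fixed at the same time. The first part took, among genes past the threshold with a mean of at least 5 CPM over all 6 libraries and groups that did not overlap, leaving out predicted genes and receptor segments, the 10 with the largest change in each direction. The second part took the member with the smallest adjusted p of each functional list in each direction. The third part took 11 genes whatever their result, among them Cd44, Itga4, Il2rb, Eomes, Tbx21, Cd8a, Jak1, Jak3 and Stat5b. Some genes that the rule took are not reported here, and the gene lists were tested with all their members. If fewer than 5 genes had passed the first part in a direction, the 5 with the smallest p would have been named there. Values are given for a selection of these genes. Other members of the lists named as examples, and the genes of the marker plot, were chosen after their values were seen.

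Summed CPM of other cell types' markers, shares of counts, and V gene measures were computed per library over all counted reads and compared with exact two-sided permutation tests over 20 assignments. The alternatives were other scalings (DESeq2 size factors, upper quartile, library size), other low-count filters, leaving out each library, a replicate block, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, stricter thresholds, protein-coding genes alone, fry and an estimated correlation. For shares and V genes they were leaving out receptor segments or a library, the 10 most abundant genes, a minimum of 10 counts and thinned counts. Scaling to 20 T cell genes and thinning to the smallest V gene total were chosen after seeing the data. Replicate numbers come from the sample titles. Libraries with the same number deviated together from their group means (r = 0.349, 0.314 and 0.125 across genes for numbers 1, 2 and 3). Pairs with different numbers ran from -0.36 to 0.113, the highest being TCM replicate 3 with TVM replicate 2. Deviations from a mean of 3 libraries depend on each other, so the numbers may pair the samples, but these values are weak evidence. Only the replicate block used the numbers, and the main tests did not.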

Results

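Gene expression was measured by RNA-seq in 6 mouse spleen libraries. According to their titles, 3 came from virtual memory CD8 T cells (TVM) and 3 from central memory CD8 T cells (TCM). Virtual memory cells carry a memory phenotype without having met foreign antigen and depend on IL-15, whereas central memory cells descend from cells that responded to antigen. The TVM libraries held 35441055, 41786184 and 41026339 counted reads, and the TCM libraries 36107545, 26326971 and 29134739. Levels are given as CPM, which are counts scaled to the size of the library, as mean ± SD (n = 3 per group), and log2 fold changes as TVM minus TCM ± SE. The first principal component held 67.8% of the variance and separated the groups.

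The comparison asks how the transcriptomes of the 2 memory populations differ. Gene lists of T cells, natural killer (NK) cell receptors and cytotoxic effectors were higher in the TVM libraries, and those of neutrophils, monocytes, dendritic cells, red cell precursors and the cell cycle were lower. These list calls, made with camera and a preset correlation, were all lost with an estimated correlation (adjusted p = 0.211 to adjusted p = 0.417). Fn1 (ENSMUSG00000026193), which encodes fibronectin, stood at 1101 ± 62.5 CPM in TCM and 1.92 ± 1.81 CPM in TVM. Lyz2, the lysozyme of myeloid cells, stood at 10760 ± 3760 CPM in TCM and 141 ± 143 CPM in TVM. In the other direction, Xcl1 (ENSMUSG00000026573), a chemokine made by CD8 T and NK cells, rose from 6.06 ± 2.46 to 55.3 ± 22.8 CPM.

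Of 16180 genes tested with edgeR's quasi-likelihood test, 2053 were higher and 2778 lower in TVM at a Benjamini-Hochberg adjusted p under 0.05. Of these, 979 were higher and 2071 lower by at least 2-fold, and 63 higher and 663 lower by at least 8-fold. The 3 TVM values lay all above or all below the 3 TCM values for 7757 genes, 47.9% of those tested, where chance gives 10%. The count of higher genes was 1189 without TCM replicate 2, 1102 without TCM replicate 3 and 1157 without TVM replicate 3. When the libraries were instead scaled to 20 T cell genes, a setting chosen after seeing the data, the median log2 fold change of all genes moved by -1.79, and 35 genes were higher and 13204 lower. This left 0.264% of the calls on the higher side, against 42.5% with the main scaling, and 32 of the 2053 genes stayed higher while all 2778 stayed lower.

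Among genes with a mean of at least 5 CPM and groups that did not overlap, leaving out predicted genes, clone names and receptor segments, the largest rise was that of Nsg2, a neuronal vesicle protein gene, with a log2 fold change of 3.72 ± 0.318 (edgeR adjusted p = 0.000241). Others among the 10 largest rises were Xcl1 at 3.19 ± 0.393 (adjusted p = 0.000982), the CD200 receptor family gene Cd200r3 at 3.11 ± 0.215 (adjusted p = 0.000192) and Crtam, an adhesion receptor of activated T and NK cells, at 2.62 ± 0.201 (adjusted p = 0.0002). Nsg2, Xcl1 and Cd200r3 also stayed higher with scaling to the T cell genes, at 2.06, 1.37 and 1.37, whereas Crtam was then at 0.90 (adjusted p = 0.0543). On the lower side, Arhgef37 had 13652 counts in the TCM libraries together and 18 in the TVM libraries (log2 fold change -9.98 ± 0.561, adjusted p = 0.00013). Fn1 was 566-fold lower, the coagulation factor genes F10 and F13a1 were 209-fold and 127-fold lower, and the ficolin gene Fcnb, expressed by neutrophil precursors, was 171-fold lower. These folds moved with single TVM libraries and with the method. Without TVM replicate 2, the log2 fold change of Fn1 went from -9.14 to -10.30 and the log2 fold change of F13a1 from -6.99 to -8.99. The log2 fold change of Fcnb, -7.42 in edgeR, was -8.02 without TVM replicate 1, -6.82 without TVM replicate 3 and -11.01 for limma-voom with quality weights. With the same weights the log2 fold change of F10 went from -7.71 to -8.60, and with limma-voom the log2 fold change of Arhgef37 was -10.57.

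**Figure D1:**
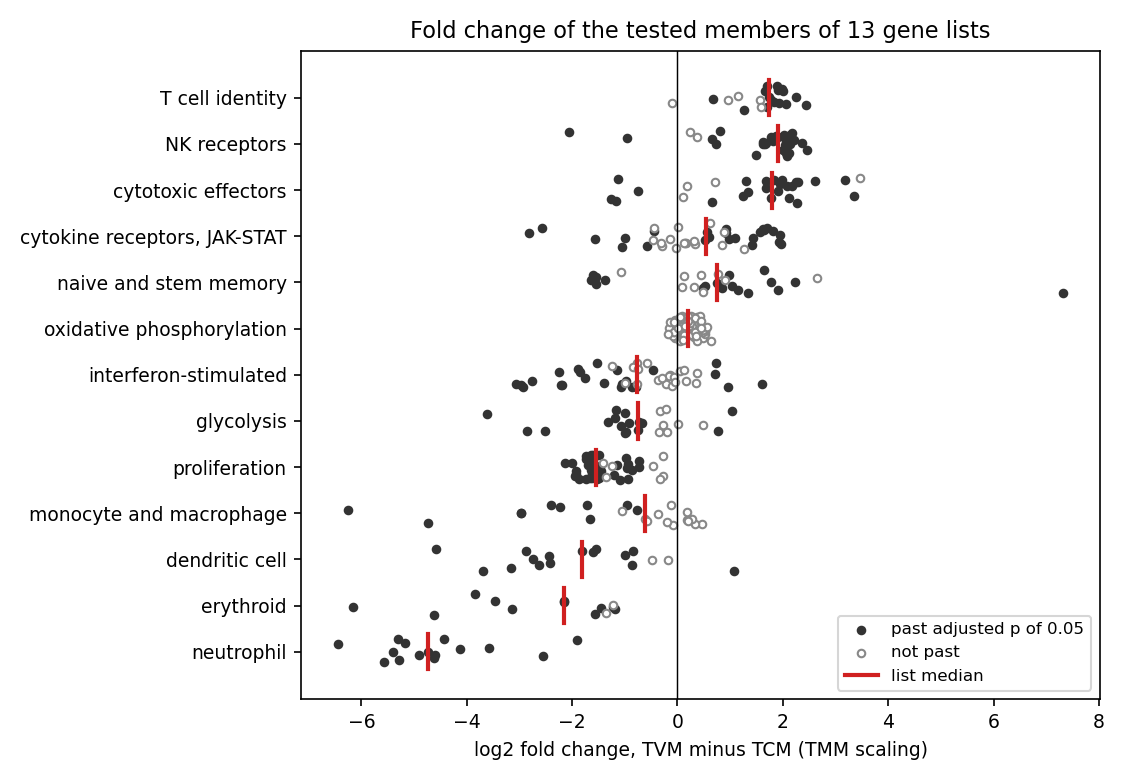
Log2 fold change (horizontal axis, TVM minus TCM, TMM scaling) of each tested member of 13 gene lists, 1 point per gene, with filled points past an adjusted p of 0.05 in edgeR and a red bar at each list's median. The medians run from -4.74 for neutrophil genes to 1.92 for NK receptor genes; scaling to the T cell genes moves the median of all genes by -1.79, which turns the medians of the cytotoxic, cytokine receptor, naive and stem memory and oxidative phosphorylation lists below 0.

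T cell genes were higher in the TVM libraries as a group. Of 21 T cell identity genes, 16 rose, 0 fell and 5 did not pass the threshold, with a median log2 fold change of 1.75. Scaling to 20 of these genes sets that median close to 0, at 0.05. Adjusted over the list alone, 18 rose, and with a replicate block 20 rose and 0 fell. The list was past the threshold in camera (adjusted p = 4.69e-14) but not with an estimated correlation (adjusted p = 0.211). The receptor constant gene Trbc1 rose from 67.9 to 369 CPM, Cd2 from 87.6 to 415 CPM, and the receptor kinase gene Zap70 by 2.01 ± 0.155 (edgeR adjusted p = 0.000203). Reads of Trbc1 can be shared with the near-identical Trbc2, which rose by 2.06. Cd8a, which encodes the coreceptor that defines both populations, had 102 ± 46.8 CPM in TCM and 244 ± 97.2 CPM in TVM (log2 fold change 1.26 ± 0.401, edgeR adjusted p = 0.0493). That call was lost in 7 of 15 other settings, among them those without TCM replicate 1 (adjusted p = 0.101), TCM replicate 3 (0.129), TVM replicate 2 (0.0974) and TVM replicate 3 (0.0984). Its adjusted p in these settings ranged from 0.000691, with a replicate block (log2 fold change 1.30 ± 0.126), to 0.129. Its log2 fold change was -0.42 when scaled to the T cell genes. Cd3e, at 1.57 ± 0.573, did not pass (adjusted p = 0.0767), but passed with a replicate block (1.64 ± 0.147, adjusted p = 0.000546), as its spread was shared by replicate number (6.69, 29.8 and 17.8 CPM in TCM and 26.0, 84.7 and 49.8 CPM in TVM).

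NK cell genes were higher in TVM. Of 31 NK receptor genes, 27 rose, 2 fell and 2 did not pass, with a median log2 fold change of 1.92; the counts adjusted over the list alone were also 27 and 2. Camera gave an adjusted p of 3.64e-19, which became an adjusted p of 0.311 with an estimated correlation. Ncr1, which encodes the NK receptor NKp46, rose from 268 ± 60.8 to 976 ± 134 CPM, and Klrb1c, which encodes NK1.1, from 190 ± 42.5 to 781 ± 233 CPM. Cd160 rose by 2.46 ± 0.155 (edgeR adjusted p = 0.000187). Klra17 and Fcgr3, both also expressed by myeloid cells, fell. Members of the Klra family are close paralogs, and the reads of single members are uncertain. Ncr1 stood at 7.05, 2.40 and 4.37 times the level of Cd8a in the TVM libraries and at 6.39, 1.57 and 2.19 times in the TCM libraries. A list of NK and innate lymphoid cell markers, of which 13 of 17 genes also belong to other lists, had 9 of 16 tested genes higher and 0 lower, also when adjusted over the list alone (median 1.83, camera adjusted p = 1.04e-06, and adjusted p = 0.316 with an estimated correlation). With scaling to the T cell genes, 0 of the 27 NK receptor genes stayed higher in edgeR, where 32 of all 2053 higher genes did, and their median log2 fold change was 0.22.

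**Figure D2:**
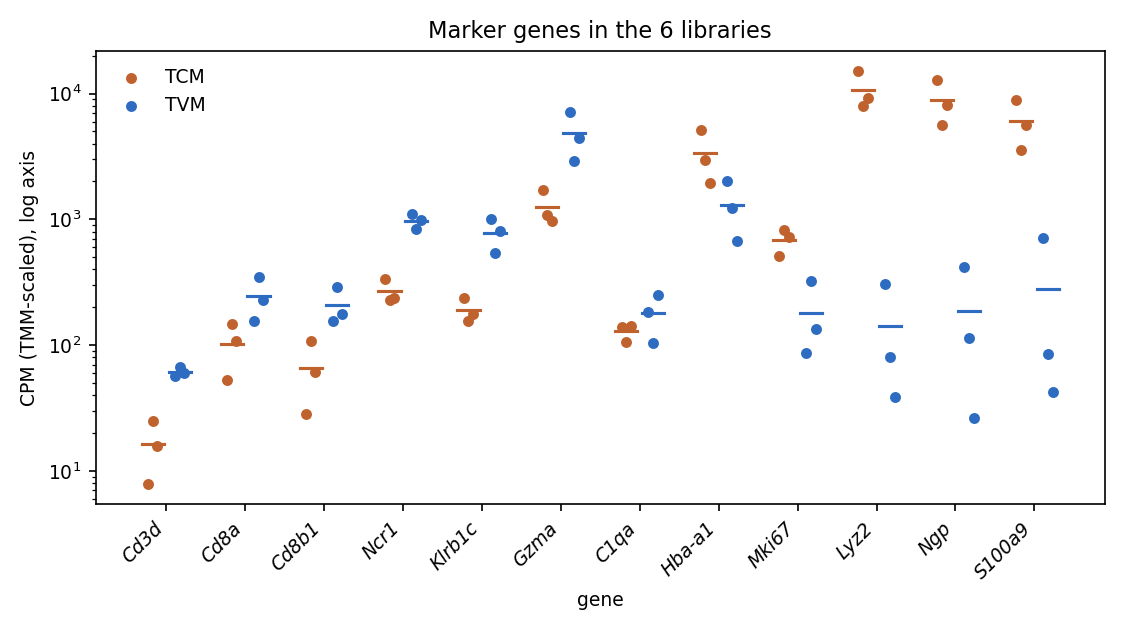
Level of 12 genes in each library (vertical axis, TMM-scaled CPM on a log scale), with 1 point per library and a bar at the mean of each group of 3. The T cell genes Cd3d, Cd8a and Cd8b1 and the NK genes Ncr1 and Klrb1c lie higher in TVM, a direction that turns for Cd8a with scaling to the T cell genes, and Lyz2, Ngp and S100a9 lie lower.

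Cytotoxic effector genes were higher in TVM, and their median turned to -0.01 with scaling to the T cell genes. Of 28 tested members, 20 rose, 4 fell and 4 did not pass (21 and 4 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 1.19e-09, and adjusted p = 0.316 with an estimated correlation). Gzma, which encodes granzyme A, rose from 1253 ± 395 to 4840 ± 2140 CPM, the perforin gene Prf1 from 338 ± 108 to 1198 ± 370 CPM (-0.02 on the log2 scale with scaling to the T cell genes), and the interferon-γ gene Ifng by 2.25 ± 0.347 (edgeR adjusted p = 0.00258). Lamp1, Ccl9, Tnf and Ctsc fell, with Lamp1, a lysosomal membrane protein gene, at -1.27 ± 0.167 (adjusted p = 0.00133). NK receptor genes and neutrophil genes moved with this list, the former up and the latter down. With scaling to the T cell genes the cytotoxic list still passed in camera as higher relative to the other genes (adjusted p = 4.67e-10).

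Genes of the common γ chain cytokine receptors and of JAK-STAT signalling, the route of IL-15, were more often higher than lower, with a median of 0.54 that became -1.26 with scaling to the T cell genes. Of 40 members, 17 rose, 7 fell and 16 did not pass (18 and 7 adjusted over the list alone). Camera gave an adjusted p of 0.000906, and an adjusted p of 0.355 with an estimated correlation. The list did not pass in camera with scaling to the T cell genes (adjusted p = 0.103). Il2rb (ENSMUSG00000068227), the β chain of the IL-2 and IL-15 receptors, rose from 576 ± 84.4 to 2205 ± 39.7 CPM (log2 fold change 1.94 ± 0.158, edgeR adjusted p = 0.000214), and stood at 0.12 with scaling to the T cell genes. The receptor-associated kinase genes Jak1 and Jak3 rose by 1.10 ± 0.141 and 0.91 ± 0.156 (adjusted p = 0.00117 and 0.00407), but stood at -0.72 and -0.92 when scaled to the T cell genes. Bcl2, which encodes a survival factor, rose by 1.57 ± 0.139 and stood at -0.22 with scaling to the T cell genes. Stat5b fell by 0.59 ± 0.121 (adjusted p = 0.00915), a call lost without TVM replicate 3 (adjusted p = 0.0524, with 0.0007 to 0.0524 over 15 settings). Il6ra fell by 2.82 ± 0.189 (adjusted p = 0.000192) and Ifngr2 by 2.56 ± 0.19. In the same libraries NK receptor genes rose (median 1.92) and neutrophil genes fell (median -4.74).

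Genes of naive and stem-like memory cells were divided. Of 27 members, 13 rose, 5 fell and 9 did not pass (16 and 5 adjusted over the list alone), with a median of 0.75 that became -1.08 with scaling to the T cell genes (camera adjusted p = 0.00051, and adjusted p = 0.333 with an estimated correlation). Tcf7, which encodes the transcription factor TCF-1, rose from 75.8 ± 15.9 to 357 ± 20.6 CPM (2.24 ± 0.165, edgeR adjusted p = 0.000192). With scaling to the T cell genes it stood at 0.51 and did not pass (adjusted p = 0.287). Dapl1 had 4 counts in the TCM libraries together and 946 in the TVM libraries, and stayed higher with scaling to the T cell genes. Bcl6 fell by 1.54 ± 0.2 (adjusted p = 0.00124). Of 24 effector transcription factor genes, 10 rose, 2 fell and 12 did not pass (11 and 2 adjusted over the list alone), with a median of 0.56, or -1.21 with scaling to the T cell genes (camera adjusted p = 0.000786, and adjusted p = 0.211 with an estimated correlation). Eomes and Tbx21, which encode the T-box factors of memory and effector lymphocytes, rose by 1.93 ± 0.196 (adjusted p = 0.000454) and 1.81 ± 0.198 (adjusted p = 0.000608). With scaling to the T cell genes they stood at 0.13 and 0.02. The effector transcription factor list did not pass in camera with that scaling (adjusted p = 0.0581). Batf3, a dendritic cell factor, fell by 1.61 ± 0.324 (adjusted p = 0.00831).

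Among 10 surface markers commonly used to gate memory CD8 T cells, 6 rose, 2 fell and 2 did not pass (6 and 3 adjusted over the list alone). As a list they did not pass in camera (adjusted p = 0.0538), with a median of 0.81, or -1.01 with scaling to the T cell genes. The list passed with a replicate block (adjusted p = 0.0154), without TCM replicate 1 (0.0231) or TVM replicate 3 (0.0326). It also passed with upper quartile scaling (0.0478), library size only (0.0467), no low-count filter (0.0126) or at least 5 CPM in 3 libraries (0.0462). It did not pass with an estimated correlation (adjusted p = 0.333) or, in camera, with scaling to the T cell genes (adjusted p = 0.152). The range was 0.0126 to 0.0818 over the planned settings with a preset correlation. Cd44 fell from 520 ± 76.7 to 301 ± 64.0 CPM (-0.79 ± 0.183, edgeR adjusted p = 0.0151), and its call was lost without TVM replicate 3 (adjusted p = 0.0647, with 0.000421 to 0.0647 over 15 settings). Itga4, which encodes CD49d, had a log2 fold change of -0.29 ± 0.233 and did not pass (adjusted p = 0.39). With scaling to the T cell genes it stood at -2.12 and passed (edgeR adjusted p = 0.000149). Ly6c2 fell by 1.49 ± 0.275 (adjusted p = 0.00571), with reads that its paralog Ly6c1 can share.

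Of 42 migration and adhesion genes, 16 rose, 9 fell and 17 did not pass (19 and 10 adjusted over the list alone), with a median of 0.65, or -1.15 with scaling to the T cell genes (camera adjusted p = 0.00973, and adjusted p = 0.311 with an estimated correlation). Cxcr3, a receptor of effector and memory T cells, rose by 1.77 ± 0.314 (edgeR adjusted p = 0.00481). Xcr1, the receptor for Xcl1 on dendritic cells, fell by 4.58 ± 0.627 (adjusted p = 0.00153). The migration and adhesion list did not pass in camera with scaling to the T cell genes (adjusted p = 0.08). Of 18 tissue residency genes, 7 rose, 5 fell and 6 did not pass (9 and 5 adjusted over the list alone). Of 25 inhibitory receptor and exhaustion genes, 7 rose, 5 fell and 13 did not pass (9 and 6 adjusted over the list alone). Neither of these 2 lists passed in camera (adjusted p = 0.298 and 0.133). Among inhibitory genes, Tigit rose by 1.31 ± 0.28 (edgeR adjusted p = 0.0106), whereas Pdcd1 was at 0.12 ± 0.462 (adjusted p = 0.872) and Lag3 at -0.23 ± 0.163 (adjusted p = 0.341). With scaling to the T cell genes Tigit stood at -0.43, and Pdcd1 and Lag3 passed as lower, at -1.53 (edgeR adjusted p = 0.0063) and -2.03 (adjusted p = 3.36e-05).

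Cell cycle genes were lower in the TVM libraries. Of 44 proliferation genes, 37 fell, 0 rose and 7 did not pass (41 fell adjusted over the list alone), with a median of -1.55 (camera adjusted p = 1.19e-09, and adjusted p = 0.417 with an estimated correlation). Mki67, which encodes the proliferation marker Ki-67, fell from 685 ± 160 to 181 ± 125 CPM. Glycolysis genes were also lower, with 14 of 23 falling, 2 rising and 7 not passing (15 and 2 adjusted over the list alone), a median of -0.76, and camera adjusted p of 0.000189, or an adjusted p of 0.341 with an estimated correlation. The hexokinase gene Hk2 fell by 2.86 ± 0.172 (edgeR adjusted p = 0.000178), and Pfkp rose by 1.04 ± 0.125 (adjusted p = 0.000868), turning to -0.76 with scaling to the T cell genes. None of 69 oxidative phosphorylation genes passed, with or without adjustment over the list alone (1 with a replicate block), and their median was 0.21, or -1.57 with scaling to the T cell genes. That list was past the threshold in camera (adjusted p = 0.0494, and adjusted p = 0.801 with an estimated correlation). It did not pass without TCM replicate 2 (adjusted p = 0.0552), TCM replicate 3 (0.0766) or TVM replicate 1 (0.547). Nor did it pass with DESeq2 size factors (0.0531), at least 5 CPM in 3 libraries (0.105) or scaling to the T cell genes (0.666). The range was 0.000252 to 0.547 over the planned edgeR settings with a preset correlation. Of 24 fatty acid oxidation genes, 4 rose, 5 fell and 15 did not pass, also when adjusted over the list alone, and the list did not pass (median 0.03 with a camera direction of lower, adjusted p = 0.598). The median of this list was -1.75 with scaling to the T cell genes, where 0 members were higher and 22 lower. Its scavenger receptor gene Cd36 fell by 3.74 ± 0.351 (adjusted p = 0.000332). Neutrophil and red cell precursor genes fell in the same libraries.

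Of 43 interferon-stimulated genes, 19 fell, 4 rose and 20 did not pass (22 and 5 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 0.000634, and adjusted p = 0.574 with an estimated correlation). Neutrophil genes (median -4.74) and the myeloid genes Lyz2 (-6.26) and Cybb (-4.74) fell in the same libraries. Ifi204 fell by 3.07 ± 0.317 (edgeR adjusted p = 0.000478) and Oas2, which encodes an antiviral oligoadenylate synthetase, from 219 to 27.8 CPM. Ifi208 rose by 1.60 ± 0.153 (adjusted p = 0.000357) and stood at -0.22 with scaling to the T cell genes. Ifi204 and Ifi208 belong to a cluster of paralogs that can share reads. Of 21 tested genes of steroid and insulin receptors and steroid metabolism, 2 rose, 6 fell and 13 did not pass, also when adjusted over the list alone, and the list did not pass in camera (median -0.27, adjusted p = 0.325). Cyp11a1, which encodes the enzyme of the first step of steroid synthesis, rose from 4.84 ± 0.69 to 29.0 ± 5.62 CPM (2.58 ± 0.213, adjusted p = 0.000214), and stood at 0.76 with scaling to the T cell genes. The insulin receptor gene Insr fell by 1.52 ± 0.234 and Igf1r by 1.90 ± 0.269.

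Myeloid genes were lower in TVM in part of the lists. All 15 neutrophil genes fell, also when adjusted over the list alone, with a median of -4.74 (camera adjusted p = 3.4e-09, and adjusted p = 0.327 with an estimated correlation). The median was -6.62 without TVM replicate 1, which held 2509 summed CPM of these genes against 503 and 222 in TVM replicates 2 and 3. The granule protein gene Ngp stood at 8877 ± 3670 CPM in TCM and 186 ± 205 CPM in TVM, and S100a9 at 6030 ± 2680 and 280 ± 374 CPM. Of 23 monocyte and macrophage genes, 10 fell, 0 rose and 13 did not pass, also when adjusted over the list alone (median -0.62, camera adjusted p = 2.07e-05, and adjusted p = 0.372 with an estimated correlation). Those that fell included Lyz2 and the phagocyte oxidase gene Cybb at -4.74 ± 0.242. The tissue macrophage genes C1qa and Vcam1 stood at 0.47 ± 0.292 (edgeR adjusted p = 0.267) and 0.20 ± 0.276 (adjusted p = 0.629). Of 17 dendritic cell genes, 14 fell and 1 rose, also when adjusted over the list alone (median -1.82, camera adjusted p = 2.73e-09, and adjusted p = 0.211 with an estimated correlation). The riser was Itgax, which NK cells and some T cells also express, at 1.07 ± 0.119, or -0.71 with scaling to the T cell genes.

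Erythroid genes were lower in TVM, with 11 of 13 falling and 13 falling when adjusted over the list alone (median -2.14, camera adjusted p = 5.8e-09, and adjusted p = 0.311 with an estimated correlation). Klf1, the transcription factor gene of red cell precursors, fell by 4.63 ± 0.545 (edgeR adjusted p = 0.000805), while the haemoglobin gene Hba-a1, whose reads can be shared with Hba-a2, stood at -1.36 ± 0.466 (adjusted p = 0.0617, or 0.000621 with a replicate block). Of 9 platelet genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.194). Of 10 stroma and endothelium genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -1.87). That list passed in camera (adjusted p = 0.0414, and adjusted p = 0.341 with an estimated correlation) but not without TCM replicate 1 (adjusted p = 0.0598), TCM replicate 3 (0.0951) or TVM replicate 1 (0.0509), nor with at least 5 CPM in 3 libraries (0.245), with a range of 0.014 to 0.245 over the settings with a preset correlation.

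Of 20 tested B cell genes, 5 fell and 0 rose, also when adjusted over the list alone. These were Cd74, H2-Aa, H2-Ab1 and H2-Eb1, which all antigen-presenting cells express, and Ly6d. The list passed in camera (median -0.54, adjusted p = 0.0107, and adjusted p = 0.541 with an estimated correlation), but not without TVM replicate 1 (median -0.06, adjusted p = 0.139), and its median was -1.90 without TVM replicate 2, with a range of 0.000252 to 0.139 over the settings with a preset correlation. Of 5 tested plasma cell genes 1 fell, also when adjusted over the list alone (camera adjusted p = 0.555). Of 12 CD4 T cell genes, 2 rose and 1 fell, also when adjusted over the list alone, or 5 and 2 with a replicate block (camera adjusted p = 0.0861). That list passed without TVM replicate 1 (adjusted p = 0.0176) or TVM replicate 3 (0.0296) and with no low-count filter (0.0243). It did not pass with an estimated correlation (adjusted p = 0.515). The range was 0.0176 to 0.406 over the planned settings with a preset correlation. With scaling to the T cell genes the list passed in camera as higher relative to the other genes (adjusted p = 0.00459), at a median of -0.83. Of 10 γδ and NKT cell genes, 3 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.298), with a median of -0.24 and a camera direction of higher. With only genes of at least 5 CPM in 3 libraries, that list passed (adjusted p = 0.00659, with 0.00659 to 0.631 over the settings with a preset correlation, and adjusted p = 0.417 with an estimated correlation) and its median turned to 1.87, and the median was -0.84 without TVM replicate 2. The δ chain constant gene Trdc rose from 23.1 ± 4.51 to 96.0 ± 20.2 CPM. Of 13 mitochondrially encoded genes none passed (adjusted p = 0.586), and of 39 early response and stress genes 7 rose and 9 fell, or 8 and 9 adjusted over the list alone (adjusted p = 0.696). Fos fell from 431 to 140 CPM and Dusp2 rose from 141 to 404 CPM, a log2 fold change of -0.27 with scaling to the T cell genes.

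The share of each library taken by markers of other cell types was compared with an exact two-sided permutation test, which cannot go below p = 0.1 for 3 libraries against 3. The 15 neutrophil genes together held 29300 ± 9870 CPM in TCM and 1080 ± 1250 CPM in TVM, and monocyte and macrophage genes 18100 ± 3520 and 3040 ± 985 CPM. Erythroid genes held 8870 ± 2930 CPM in TCM and 3380 ± 1380 CPM in TVM. The NK and innate lymphoid list moved the other way, from 2630 ± 242 CPM in TCM to 6760 ± 1670 CPM in TVM. Each of these 4 differences had the smallest p the test allows, 0.1 (0.178 after Benjamini-Hochberg adjustment over 16 measures). The summed B cell list was at 3920 ± 720 CPM in TCM and 1500 ± 531 CPM in TVM (exact p = 0.1), but Cd74, H2-Ab1, H2-Aa and H2-Eb1, which all antigen-presenting cells express, stood at 1435, 649, 582 and 461 TMM-scaled CPM in TCM and 340, 166, 140 and 140 CPM in TVM. The B lineage gene Pax5 overlapped between groups, at 18.3, 97.6 and 82.4 CPM in TCM and 1.16, 114 and 12.9 CPM in TVM (edgeR adjusted p = 0.711). Summed CD4 T cell genes were at 283 ± 8.07 and 286 ± 53.2 CPM (exact p = 1). Mitochondrial genes took 1.44 ± 0.22% of counts in TCM and 1.42 ± 0.21% in TVM (exact p = 1). Some of them were counted at low levels in both groups, with mt-Co2 at 22.5 and 26.1 CPM and mt-Co3 at 15.0 and 17.1 CPM beside mt-Co1 at 7570 and 6917 CPM, and this share is of counted reads only. In TCM and TVM, ribosomal protein genes took 2.90 ± 0.33% and 4.08 ± 0.83% (exact p = 0.1). The 50 most abundant genes took 13.1 ± 1.58% in TCM and 11.5 ± 1.01% in TVM (exact p = 0.3).

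T cell receptor V genes were counted more often in the TVM libraries. Counts of β chain V genes (Trbv) came to 1164, 3188 and 1631 in the TVM libraries and to 258, 797 and 465 in the TCM libraries (exact permutation p = 0.1, the smallest possible). Counts fell on 21.3 ± 2.89 Trbv genes in TVM and on 16.7 ± 1.53 in TCM (exact p = 0.2), and on 53.7 ± 11.6 and 27.3 ± 10.3 α chain V genes (Trav, exact p = 0.1). The most abundant Trbv gene held 19.0 ± 7.09% of Trbv counts in TVM and 22.2 ± 5.30% in TCM (exact p = 0.5), and the most abundant Trav gene 12 ± 1.58% and 25.4 ± 6.51% of Trav counts (exact p = 0.1). The evenness of Trbv counts, on a scale from 0 to 1, was 0.85 ± 0.08 in TVM and 0.79 ± 0.05 in TCM (exact p = 0.4), and that of Trav counts 0.88 ± 0.02 and 0.81 ± 0.05 (exact p = 0.2). After Benjamini-Hochberg adjustment over the 8 V gene measures, the smallest value was 0.2. The Trbv evenness difference turned to -0.02 when only genes with at least 10 counts were used, and the few V gene counts in TCM limit the number of V genes that can be seen.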

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

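Scaling to the T cell genes and thinning to the smallest V gene total were chosen after the results were seen; the other settings were fixed before the data were examined. Of 51 named genes, 47 kept their direction and their side of the threshold in all planned settings run on them, 4 changed side in some (Ppargc1a, Cd44, Cd8a and Stat5b) and 0 reversed. Genes higher in TVM numbered 2053 and genes lower 2778 in edgeR; at an adjusted p of 0.01 they numbered 961 and 1655, and with glmTreat against 1.5-fold 795 and 1701. Requiring a fold change of at least 2 left 979 higher genes, and limma-voom with quality weights called 3553. Leaving out 1 library gave 1102 (without TCM replicate 3) to 2419 (without TVM replicate 2) higher genes. With scaling to the T cell genes, 35 were higher and 13204 lower, and log2 fold changes reversed to -0.0104 for Il18r1, -0.0730 for Cd7, -0.22 for Ifi208, -0.76 for Pfkp, -0.42 for Cd8a, -0.72 for Jak1 and -0.92 for Jak3. This follows from the construction of that setting, which moves the median of all genes by -1.79. The DESeq2 Wald test shared 4598 of its 5336 calls with the 4831 of edgeR, and limma-voom 4711 of 5058. With a replicate block, 4676 of 5482 calls were shared, and the calls of the list of gate markers (adjusted p = 0.0154) and of Cd3e, Hba-a1, Dntt and Xist were gained. No other call of a list or printed gene changed, but counts of list members did. With the block, 20 instead of 16 T cell identity genes and 14 instead of 10 effector transcription factor genes were higher. Of the interferon-stimulated genes, 25 instead of 19 were lower. Early response and stress genes went from 7 higher and 9 lower to 9 and 13. Of the gene lists, 9 were higher and 9 lower with the preset correlation, and 0 and 0 with an estimated correlation. The fry test called 19 lists, but not the same ones. It lost the interferon-stimulated (fry adjusted p = 0.0849), oxidative phosphorylation (0.459) and B cell (0.0818) lists. It gained the gate marker (fry adjusted p = 0.0076), inhibitory and exhaustion (0.0107), steroid and insulin receptor (0.0101) and platelet (0.0132) lists. The platelet median reversed to 0.213 with at least 5 CPM in 3 libraries, where fewer of its genes were tested. The median of early response and stress genes ran from -0.142 (without TVM replicate 1) to 0.0932 (without TVM replicate 3). The TVM minus TCM difference in the percent of mitochondrial counts ran from -0.147 (without TCM replicate 1) to 0.0789 (without TVM replicate 1). The difference in Trbv evenness turned from 0.0569 to -0.0199 with genes of at least 10 counts. For these last 3 the cause was not tested. The V gene measures rest on few counts, with 258 Trbv and 58 Trav counts in TCM replicate 1.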

Other observations

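The tests of granulocyte transcripts, of B cell stages, of list members against all genes, of NK genes against T cell genes, of library order and of Xist, and the gene families described here, were chosen after the results were seen. The B cell stage test replaced a comparison of B lineage with neutrophil genes, and the library order test was first run on fewer NK genes; both were redefined after their first outcome was known. The tests of list members and of NK against T cell genes replaced tests written before the results, whose outcome the scaling to the T cell genes had fixed or nearly fixed. The test of list members was first run on upper quartiles, which left monocyte and macrophage genes undecided (0.0178 from the median of all genes). The readings of the granulocyte, library order and T and B cell Xist tests were lowered to undecided after their outcomes were known. Of 13 gene families looked at, the Gimap family of lymphocyte GTPases had 8 of 8 tested members higher in TVM in edgeR, with a median log2 fold change of 1.84, or 0.08 with scaling to the T cell genes. The Gbp family of interferon-inducible GTPases had 6 of 10 higher and 0 lower, with a median of 1.03 that turned to -0.85 with scaling to the T cell genes. Toll-like receptor genes had 10 of 12 lower (median -2.76), Cd300 genes 8 of 8 lower (median -2.40) and coagulation factor genes 5 of 7 lower (median -4.05), and these 3 medians stayed below 0 in each scaling.

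Genes of B cell precursors varied between libraries. The B cell genes Ms4a1, Igkc and Cr2 were low, whereas Ighm stood at 374 ± 116 CPM in TCM and 356 ± 151 CPM in TVM. Dntt, the terminal transferase of lymphocyte precursors, stood at 168 ± 102 CPM in TCM and 85.4 ± 114 CPM in TVM (edgeR adjusted p = 0.506, or 0.0399 with a replicate block, at a log2 fold change of -2.05), with 5.64, 216 and 35.1 CPM in TVM replicates 1, 2 and 3. The surrogate light chain gene Igll1 stood at 97.5 ± 59.7 and 73.6 ± 97.0 CPM (adjusted p = 0.79), with 2.71, 184 and 34.0 CPM in those TVM libraries. The mature B cell gene Ms4a1 stood at 0.966 ± 0.829 and 0.758 ± 0.926 CPM (adjusted p = 0.791). Rag1, a recombinase gene, stood at 0.293 ± 0.372 and 0.319 ± 0.512 CPM and was not tested. The progenitor gene Cd34 was lower in TVM, at 21.5 ± 5.93 CPM in TCM and 2.13 ± 0.385 CPM in TVM (edgeR adjusted p = 0.000203).

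Neutrophil, monocyte and erythroid genes were lower in TVM. A shift in scaling moves all genes alike and is argued against as the source of the distance of these genes from the others. In these lists 15 of 15 neutrophil, 13 of 13 erythroid and 11 of 23 monocyte and macrophage genes (47.8%) lay more than 2 SE below the median of all genes. None lay above it by as much, and 25.2% of all genes lay below. The lists are those that showed the pattern, and the bound for this reading was set after the shares were seen. Whole tissue of a spleen with its mature B cells is argued against only for the mature genes chosen, Ms4a1, Cr2, Fcer2a, Igkc and Ighd. Their ratio to precursor B cell genes was at most 0.0742 in the TCM libraries. Ighm, left out of that ratio, stood at 241, 458 and 423 CPM there, above the summed precursor genes at 100, 452 and 391 CPM. The reading thus depends on the genes chosen. Tissue of a spleen lacking mature B cells stays open. RNA of granulocytes, monocytes and red cell precursors in the TCM libraries stays open, since 7 granulocyte transcripts stood at 974 CPM or more in each TCM library, which restates the pattern and does not tell this source from the group. A CD8 gate would remove such cells, but the gate is not given in the sources used here. A difference between the memory populations as the only source of the neutrophil genes is argued against. In the TCM libraries the 15 neutrophil genes summed to 43750, 19020 and 28950 TMM-scaled CPM, beside 149, 503 and 300 CPM for 10 T cell genes. For the monocyte and erythroid genes such a difference stays open.

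T cell genes and NK receptor genes were both higher in TVM. Dilution of the lymphocyte RNA by RNA of other cells in the TCM libraries stays open: when scaled to the T cell genes, 3 of the 27 NK receptor genes called higher differed from them in edgeR, but this likeness is what prompted the test and the source of the RNA is confounded with the group. The summed NK to T cell gene ratio was 24.1, 5.14 and 8.22 in the TCM libraries and 21.0, 6.42 and 13.2 in the TVM libraries, so the genes did not keep 1 ratio within a group. The ratio had the same order by replicate number in both groups, so its spread may be shared between the groups. Library order alone leaves NK cells in the libraries undecided. Of 27 NK receptor genes, 21 had the order opposite to that of 10 T cell genes over the TVM libraries and 12 over the TCM libraries. But 3 libraries a group are too few, the genes moved together, and the T cell genes had the same order in both groups. CD8 T cells with NK receptors, which virtual memory cells can carry, stay open as part of the source. Whether they are the only source is left undecided. Summed NK genes exceeded summed T cell genes in each library. But the sums set 27 NK genes, taken because they were called higher in TVM, against 10 T cell genes, so they depend on the genes chosen. Ncr1 stood at 42.3, 9.85 and 19.9 times the level of Cd3e in the TVM libraries and at 50.5, 7.72 and 13.2 times in the TCM libraries.

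Xist, transcribed from the inactive X chromosome of females, and Y-linked genes were both present in each library. Reads of X-linked homologs are argued against, since the median ratio of 4 Y-linked genes to their homologs was at least 0.249. RNA of cells from both sexes may account for it, since Xist stood at 9.08 CPM or more in each library and varied 9.30-fold within TCM and 6.69-fold within TVM, while summed Y-linked genes varied 1.43-fold over the 6 libraries. T and B cells of the other sex than the rest stay open. The order of Xist was that of T and of B cell genes in 2 of 2 groups. But with 3 libraries each and replicate numbers that may pair the groups, the matches are too few to decide. The sex of the animals is not given in the sources used here.

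Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 4831 genes in edgeR and the highest of the others 0, so 1 split gave as many. These splits are too few for a share under 0.05.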
